A study of Rattus norvegicus with 21 samples.

How the data were processed

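RNA of cerebral cortex and hippocampus was extracted with TRIzol, checked on a Fragment Analyzer and made into libraries with a stranded mRNA kit, per the labels' protocols. The tools named are fastp 0.20.0, HISAT2 2.1.0 and featureCounts 2.0.1 from Subread, per the submitters' processing notes. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. The file's column names say that counts were filtered, and the filter is not given in the sources used here.

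The authors deposited 1 table of the signal per gene and library, as read counts divided by 1 size factor per library. Every value was a whole multiple of the smallest value above 0 in its column, within 0.001 of a whole read for 100% of values in all 21 columns. In 4 columns the factor was so close to 1 that an automatic check for whole reads did not apply. The size factors recomputed from the recovered reads over all 21 libraries, with the median-of-ratios method, matched the deposited scale to within 3.6e-13%. All 21 columns matched a sample by title, and 0 columns were left over. Because a size factor rests on the median gene, a shift of most genes in one direction would be removed by this scaling.

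Groups came from the sample titles and the tissue and treatment labels. 1 library was titled as hippocampus at 24 h, and its source and tissue labels said cortex. It stayed unassigned and entered no comparison. The labels describe the rats of a group as separate animals. Both tissues came from the same study animals, and the labels do not say that a replicate number names the same rat in both tissues. Counts of the 24 pairs of libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom 15.63 to 265.2), so no library was counted as a repeat of another.

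Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold adjusted p 0.05). Genes needed a mean of at least 10 over the libraries of the fit, which left 14783 in cortex, 15028 in hippocampus and 15017 in the fit of both tissues. The 3 groups of a tissue shared 1 fit, and the tissue and interaction contrasts used all 20 libraries. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 (Wald test) were run on the recovered reads as alternatives. The tests, groups and most alternatives were chosen before the data were examined. These alternatives were the pseudocount, the filter, TMM and quantile scaling, the variance model, the libraries in the fit, a block and leaving out each library. Library weights, leaving out doubted libraries and a position covariate were added after seeing the data. A library was called doubted with an estimated weight under 0.25 or a position over 0.3 from its own tissue's end.

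The position of a library between cortex and hippocampus was the median, over genes at least 4-fold apart between the tissue medians and with a median of at least 100 in the higher tissue, of its place between those medians. The genes were chosen without the library itself. The global test permuted the libraries of a tissue over its 3 groups in all 4200 arrangements.

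The table does not pair its IDs with gene names, and the reference table of 47357 rat genes (assembly GRCr8) gave an Ensembl ID for 0 of them, so 0 IDs were paired. The 37 gene lists fixed beforehand, their set tests, and the rule for named genes could therefore not be applied. That rule took the genes with a symbol and the largest non-overlapping changes among those past the threshold, or those with the smallest p where fewer than 6 passed, and members of the lists. In its place 4 IDs are printed by a rule set after the files were seen. They are the largest non-overlapping called change in each direction between control tissues, and the smallest p in each direction for cortex at 24 h. The genomic positions of these genes and checks of GC content and gene length were not analysed here.

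The tests were run on simulated counts with 200 genes changed by known folds. limma recovered 63.6% of 4-fold changes in the simulated comparison of cortex at 24 h with control (14733 genes), with 3 false calls among 53. In the simulated hippocampus comparison at 24 h (14705 genes) it recovered 31.8%, with 1 false call among 22, and at 48 h (14715 genes) 10.6%, with 0 false calls among 7. DESeq2 made 28 false calls among 108 in the first (14783 genes) and 34 among 85 in the second (15028 genes).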

Results

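RNA was sequenced from the cerebral cortex and the hippocampus of male SD rats that had been exposed repeatedly to hypobaric hypoxia, that is, to the low air pressure and low oxygen of high altitude in a decompression chamber. Of 12 rats, 8 were exposed and 1 of these was lost. Each exposure rose to a simulated 28000 ft, held for 5 min, and 6 such cycles were given at intervals of 3 days. Tissue was taken 24 h or 48 h after the last cycle, and control rats stayed at normal oxygen. The 20 libraries with a group were 4 control, 3 at 24 h and 3 at 48 h for cortex, and the same numbers for hippocampus. A further library carried conflicting tissue labels and entered no comparison. The question addressed was which genes differ in each tissue 24 h and 48 h after repeated exposure.

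The deposited table held 30560 Ensembl rat gene IDs, of which 7193 were at 0 in all 21 libraries. It did not pair the IDs with gene names, so genes are reported as numbers of IDs and by 4 example IDs. Reads in genes ranged from 11214566 to 19304803 per library, except for hippocampus control 1 with 4654096. That library had reads in 15134 genes, and the other 20 had reads in 18502 to 19688. The median SD per gene within a group, on the log2 scale, was 0.312 in control cortex (n = 4), 0.291 in cortex at 24 h (n = 3) and 0.2 in cortex at 48 h (n = 3). In hippocampus it was 0.639 in controls (n = 4), 0.302 at 24 h (n = 3) and 0.285 at 48 h (n = 3).

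Cortex and hippocampus mostly parted along the first principal components, which held 34.6% and 23.4% of the variance. Hippocampus control 1 lay far from all other libraries, at 178 and 125.9 on these components. The others lay between -61 and 50.6 on the first and between -56.4 and 39.7 on the second. Part of both percentages is thus this 1 library and not the tissues. The shares of variance that follow include it too. Tissue made up 25.3% of the total variance, exposure group 6.82%, tissue by exposure 7.07%, and differences between libraries of a group 60.8%. Chance alone gives 5.26%, 10.5%, 10.5% and 73.7%, so both shares with exposure lay below what chance gives. In an exact permutation test of all genes together, over 4200 arrangements of the 10 libraries of a tissue, no difference between the 3 groups was found in cortex (pseudo-F 0.93, p = 0.562) or in hippocampus (pseudo-F 0.744, p = 0.897).

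**Figure D1:**
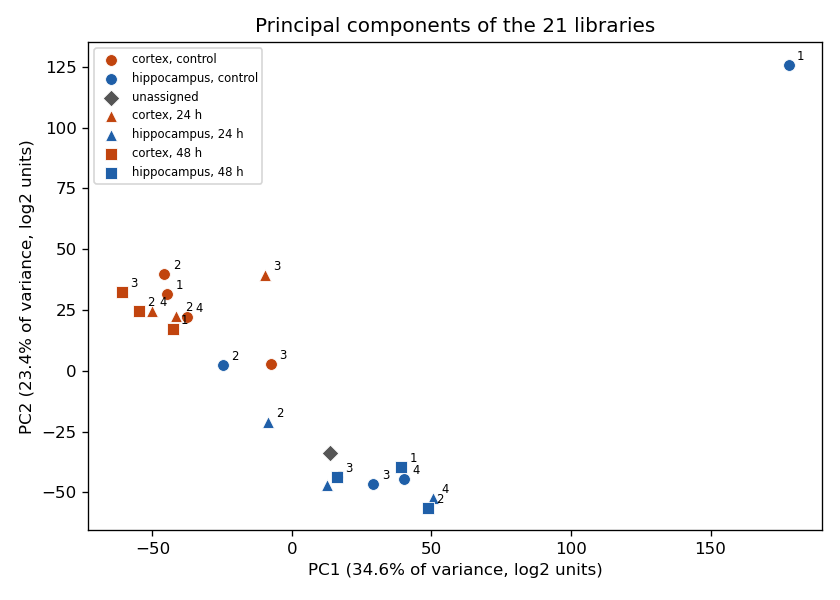
Principal components of log2 values of the 21 libraries, PC1 (34.6% of variance) against PC2 (23.4%), coloured by tissue with the exposure group as the symbol and the replicate number beside it. Hippocampus control 1 lies at 178 and 125.9. Hippocampus control 2 (-24.7 and 2.4) lies within the range of the cortex libraries on PC1 (-61 to -7.5). On PC2 it lies next to cortex control 3 (2.9).

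The comparison of the tissues in control rats shows the size of a large difference. For want of gene names, no gene known to mark a tissue was looked at. The comparison therefore does not check which tissue label is right. Of 15017 genes tested, 249 were higher in hippocampus and 187 were higher in cortex in limma at an adjusted p under 0.05. The differences were large, with a median absolute log2 change of 1.58 among the 436 called genes. 147 of them differed more than 4-fold, 81 higher in hippocampus and 66 higher in cortex. ENSRNOG00000005670 had a normalized read count of 43.4 ± 38.7 (SD, n = 4) in hippocampus and 1.16 ± 0.918 (SD, n = 4) in cortex, a log2 change of 4.06 on the log2(value + 1) scale (SE 0.72, limma adjusted p = 0.0115), higher in 4 of 4 libraries. ENSRNOG00000053562 had 60 ± 114 (SD, n = 4) in hippocampus and 419 ± 310 (SD, n = 4) in cortex, a log2 change of -5.29 on the same scale (SE 1.38, limma adjusted p = 0.0471). Its hippocampus values were 0, 3.7 and 5.45 in 3 libraries and 230.9 in hippocampus control 2. This second call was not kept by edgeR (adjusted p = 0.187), and DESeq2 gave it no adjusted p. limma lost it in 7 of the 8 fits without 1 control library, and with no filter, quantile normalization, no intensity trend or a pseudocount of 0.1. Its log2 change ran from -2.69 in edgeR to -6.84 without hippocampus control 2. Both calls were lost in a fit of the control libraries alone. Both IDs were picked among calls without overlap between the tissues, so the separation of their libraries is no further support.

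The number of genes called between the control tissues depended on the libraries in the fit, and both tissues came from the same rats. The fit of the 8 control libraries alone called 94. With replicate numbers as a block across tissues, which the labels do not tie to rats, 2 were called and neither named ID was among those called. In the fit of all groups the number was 1349 without hippocampus control 2, and 76, 153 and 154 without cortex controls 2, 1 and 4. Without hippocampus controls 4 and 3 it was 113 and 196. Without all 5 doubted libraries, chosen after seeing the data, it was 2542. DESeq2 called 910 higher and 605 lower, and edgeR called 313 and 155. At the later times, with 3 libraries a tissue, 219 genes were higher in hippocampus and 51 in cortex at 24 h, and 364 and 431 at 48 h. Of the 436 genes called in controls, 143 were called in the same direction at 24 h and 299 at 48 h, and 430 and 435 had the same sign. The 3 tissue contrasts shared each gene's estimate of the spread, so their lists of calls are not independent. 133 genes were called in the same direction in all 3 exposure groups, 112 of them higher in hippocampus and 21 higher in cortex.

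Several libraries lay off their own tissue's end of the scale set by genes that differ at least 4-fold between the tissues, on which the median of cortex is 0 and that of hippocampus is 1. Hippocampus control 2 lay at 0.43, hippocampus 24 h replicate 2 at 0.56, cortex control 3 at 0.52 and cortex 24 h replicate 3 at 0.32. The other cortex libraries lay between -0.09 and 0.09, and the other hippocampus libraries between 0.91 and 1.08. From genes high in cortex alone, these other hippocampus libraries lay between 0.92 and 1.05. From genes high in hippocampus alone they spread more, from 0.67 in 24 h replicate 3 to 1.59 in 24 h replicate 4. No difference in position between exposure groups of a tissue was found in exact permutation tests (6 comparisons, two-sided, smallest p = 0.3, all adjusted p at least 0.9). With 3 libraries against 3, as for 48 h against 24 h, the smallest p possible is 0.1.

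**Figure D2:**
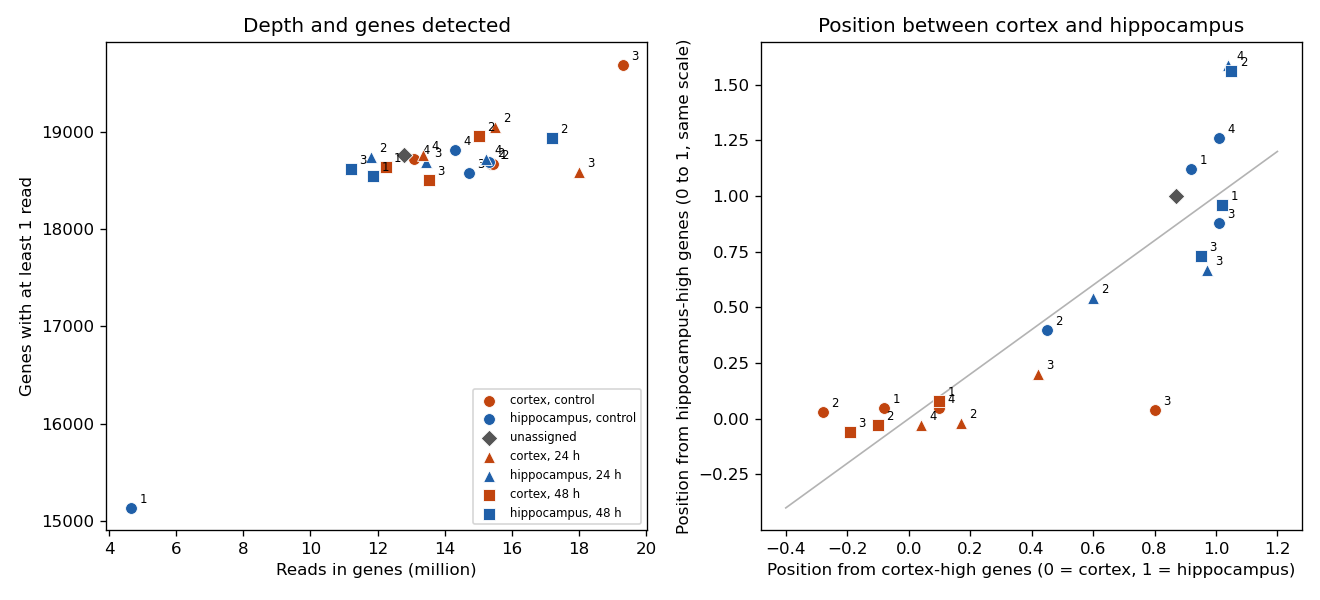
Left, reads in genes against genes with at least 1 read, 1 point per library. Right, the position of each library from genes high in cortex (x axis) and from genes high in hippocampus (y axis), where 0 is the cortex median, 1 the hippocampus median and the line marks equal values. Hippocampus control 1 has the fewest genes (15134), and cortex control 3 lies at 0.8 on the x axis and 0.04 on the y axis.

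In cortex 24 h after the last exposure, 0 of 14783 genes passed an adjusted p of 0.05 in limma, and edgeR called 0. The smallest adjusted p was 0.602. 1177 genes had an unadjusted p under 0.05 in limma, against 739 expected with no effect, and 1792 without cortex control 3. The number was 2781 with library weights, 2260 without the doubted libraries and 2014 with the tissue position as a covariate, alternatives chosen after seeing the data, each with 0 genes called. With all 20 libraries of both tissues in the fit it was 425. That fit takes its spread from both tissues, and control hippocampus varied more (median SD per gene 0.639) than the cortex groups (0.2 to 0.312). DESeq2 called 41 genes, 21 higher and 20 lower. All 41 had an unadjusted p under 0.05 in limma and moved in the same direction there. Both tests used the same reads, so this is no further support. In simulated counts for this comparison, 28 of 108 DESeq2 calls were false. Of the genes leading this comparison, ENSRNOG00000009530 had 306 ± 19.1 (SD, n = 3) at 24 h and 190 ± 8.31 (SD, n = 4) in controls, a log2 change of 0.69 (95% interval 0.4 to 0.98), above all controls in 3 of 3 libraries. ENSRNOG00000001004 had 903 ± 130 (SD, n = 3) at 24 h and 1543 ± 128 (SD, n = 4) in controls, a log2 change of -0.78 (95% interval -1.1 to -0.46), below all controls in 3 of 3 libraries. Both IDs were picked for the smallest p in their direction, so their separation from controls and their intervals are no further support. Both missed the threshold (limma adjusted p = 0.602), with DESeq2 adjusted p of 0.00387 and 0.0072.

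In cortex at 48 h, 0 genes passed in limma and in edgeR, with a smallest adjusted p of 0.885 and 515 genes at an unadjusted p under 0.05 in limma. This number was 784 without cortex control 1 and 287 without 48 h replicate 3, 152 with all 20 libraries in the fit, 1873 with library weights and 1089 without the doubted libraries. DESeq2 called 2, both lower. With both times averaged against control, limma, edgeR and DESeq2 each called 0, and 578 genes had an unadjusted p under 0.05 in limma. This number was 1233 without 24 h replicate 3, above the 739 expected, 329 without 24 h replicate 4 and 308 without 48 h replicate 3. It was 176 with all 20 libraries in the fit, 1798 with library weights and 1616 without the doubted libraries. Between 48 h and 24 h, 1675 genes had an unadjusted p under 0.05 in limma, against 739 expected, and the smallest adjusted p was 0.119. The number was 970 without 48 h replicate 1, 997 without 48 h replicate 2 and 994 without 24 h replicate 3, and 1878 at most without another library. With all 20 libraries in the fit it was 697, below the number expected, and the smallest adjusted p was 1. The spread in that fit also comes from hippocampus, including its more variable controls. limma and edgeR called 0 genes in this comparison, and DESeq2 called 18 higher and 127 lower at 48 h. limma with library weights called 1335, 609 higher and 726 lower. The weights were 0.969, 5.83 and 0.686 for 48 h replicates 1, 2 and 3. They were 2.64, 0.187 and 1.68 for 24 h replicates 2, 3 and 4. The weighted 48 h mean thus rests mostly on replicate 2, and 24 h replicate 3 counts for little. Without the 2 doubted cortex libraries, cortex control 3 and cortex 24 h replicate 3, limma called 5.

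**Figure D3:**
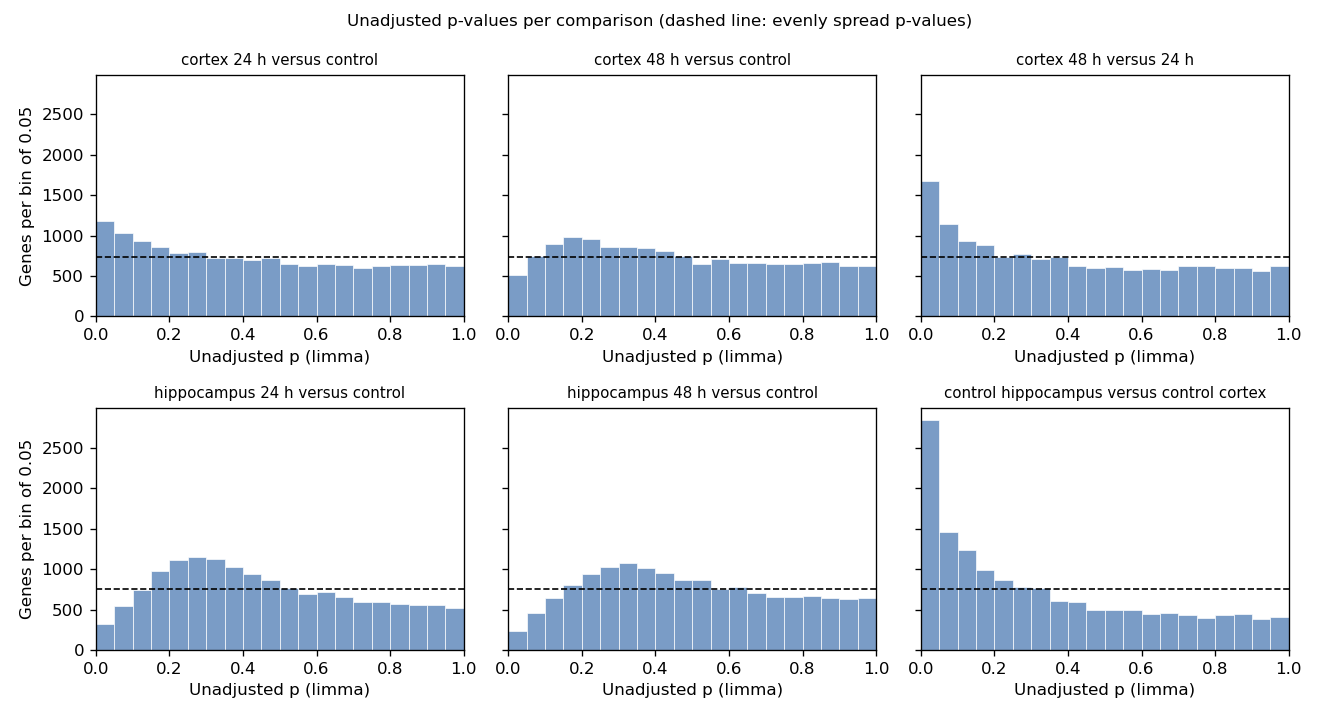
Number of genes per bin of 0.05 of the unadjusted limma p for 6 comparisons, with the dashed line at the number that evenly spread p-values give. The first bin holds 1675 genes for cortex 48 h against 24 h and 2846 for the control tissues, and fewer than the line for both hippocampus comparisons (320 and 241).

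In hippocampus, 0 of 15028 genes passed in limma and in edgeR at 24 h (smallest limma adjusted p = 0.851), at 48 h (0.928), between 48 h and 24 h (1) and for both times against control (0.769). The numbers at an unadjusted p under 0.05 in these limma fits were 320, 241, 25 and 480, against 751 expected with no effect. In edgeR they were 587, 465, 57 and 1143 of 15290 genes, and in DESeq2 904, 741, 127 and 1360 of 21389. The 751 expected holds for the 15028 genes of limma, and more are expected by chance where more genes are tested. DESeq2 called 2, 3, 1 and 9 genes. Single libraries moved the limma numbers. At 24 h the number was 531 without 24 h replicate 4, 151 without replicate 2 and 165 without replicate 3. At 48 h it was 434 and 406 without controls 1 and 3, and 77 without 48 h replicate 3. Between the times it was 238 and 13 without 24 h replicates 4 and 2, and 51 and 102 without 48 h replicates 2 and 3. For both times it was 768 without control 3, 303 without 24 h replicate 3 and 229 without 48 h replicate 3. With all 20 libraries in the fit it was 797 at 24 h, 602 at 48 h, 41 between the times and 1278 for both times. With library weights it was 1616 at 24 h, 586 at 48 h, 1716 between the times and 862 for both times, with 0 genes called. Without the doubted libraries it was 235, 301, 71 and 342, also with 0 called. The spread limited what could be seen. The median 95% interval of a log2 change reached 0.882 to either side in hippocampus and 0.535 in cortex, for an exposure time against control. In hippocampus the interval lay within a 2-fold change in either direction for 35.9% of genes at 24 h and 37.3% at 48 h. In cortex it did so for 66.4% and 67.2%.

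To see what size of change would have been called, known changes were put into the real values of 200 genes with a mean of at least 50 and tested with limma. In cortex at 24 h, 36.2% of 2-fold, 84.1% of 4-fold and 94.7% of 8-fold changes were called. At 48 h in cortex the shares were 35.6%, 87.3% and 95.7%. In hippocampus, 0% of 2-fold, 61.8% of 4-fold and 81.5% of 8-fold changes were called at 24 h, and 0%, 60.9% and 81.4% at 48 h. In the simulated counts, limma recovered fewer 4-fold changes, 31.8% at 24 h and 10.6% at 48 h in hippocampus. In cortex these were 63.6% and 71.2%. The 2 kinds of run are not alike. The simulated counts changed 66 of the 200 genes by 4-fold and the rest by 1.5-fold or 2-fold, up or down, among genes with a mean of at least 10. The added changes raised all 200 genes by the same fold. How much each difference contributed to the gap was not tested.

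The response was also compared between the tissues, as an interaction term. limma, edgeR and DESeq2 each called 0 of the genes tested for a difference in the 24 h response and for one in the 48 h response. In limma 522 and 198 genes had an unadjusted p under 0.05, against 751 expected, and the smallest adjusted p were 0.856 and 0.998. In edgeR there were 989 and 417 of 15934 genes, and in DESeq2 1158 and 624 of 22794. The 751 expected holds for the 15017 genes of limma, and more are expected by chance where more genes are tested. In limma with library weights there were 2363 and 829. Without the doubted libraries there were 594 and 483. In limma the number at 24 h was 792 and 1015 without hippocampus controls 2 and 4, and 303, 256 and 987 without hippocampus 24 h replicates 2, 3 and 4. At 48 h it was 408, 366 and 397 without hippocampus controls 1, 3 and 4. It was 86 without cortex control 3, and 101 and 124 without 48 h replicate 3 of cortex and of hippocampus. The median 95% interval of this difference reached 1.05 to either side on the log2 scale.

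The changes at 24 h and at 48 h share their control libraries. Across genes, which are not independent replicates, the log2 changes at both times correlated at r = 0.303 in cortex, with a covariance of 0.0435. Simulated unchanged groups that share their controls gave a mean r of 0.411 and a mean covariance of 0.0719. In hippocampus r was 0.83 and the covariance 0.324, against simulated means of 0.385 and 0.191. The central 95% of the simulated values reached up to 0.935 and 0.901. With the 4 controls split into pairs, each serving 1 time, the mean r over 6 splits was -0.188 in cortex and 0.0627 in hippocampus. limma and edgeR called 0 genes at either time, so 0 at both.

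**Figure D4:**
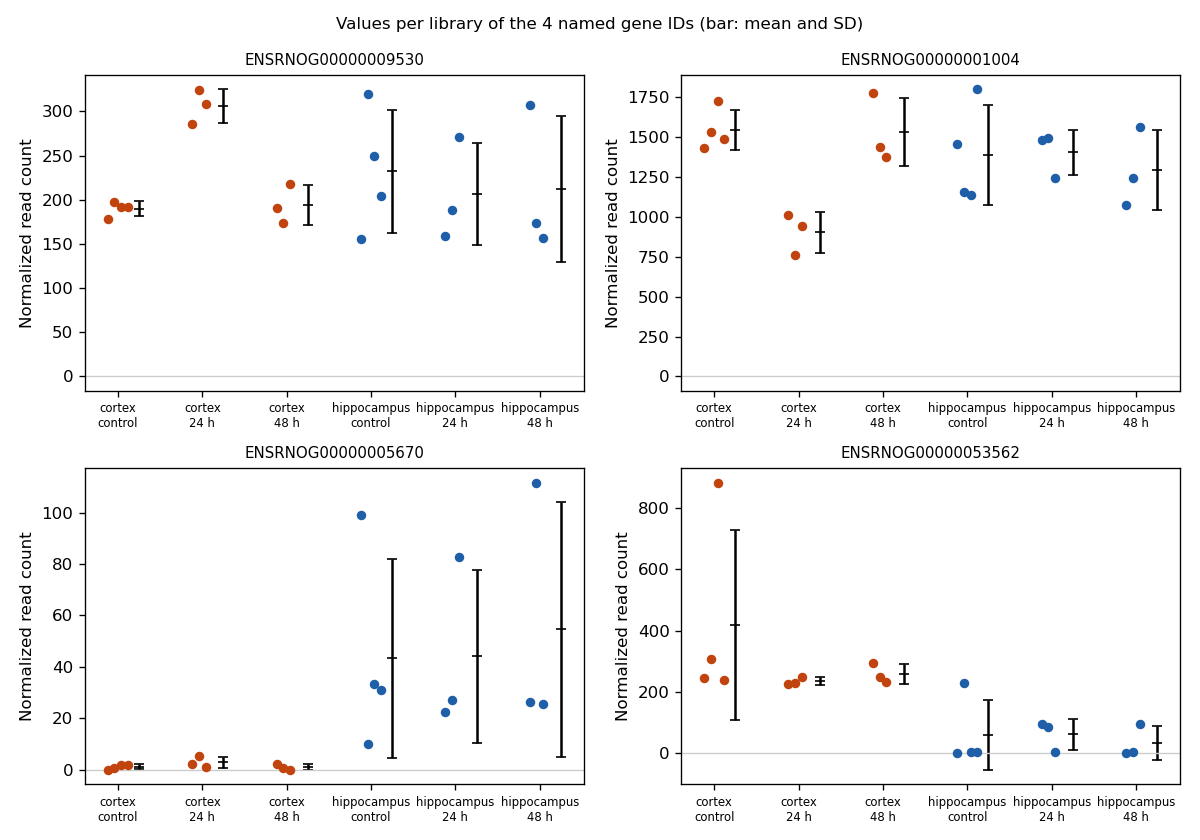
Normalized read count per library of the 4 named gene IDs in the 6 groups, with points for libraries and a bar for the mean and SD beside them. ENSRNOG00000009530 and ENSRNOG00000001004 stand apart in cortex at 24 h (306 and 903) from control cortex (190 and 1543). ENSRNOG00000053562 lies at 230.9 in hippocampus control 2 and at 880.9 in cortex control 3.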

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

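The tests of explanations below were chosen only after the results were seen, except the test of few starting molecules and the counts of other splits without library weights. Several measures were each tested in both groups of 4 control libraries for a library far from the other 3. Of these 22 tests, 8 flagged a library, and chance gives about 1 in 20. The measures overlap and include IDs picked from these data, so the tests are not independent. Groups of 3 were not tested. Hippocampus control 1 stood apart in reads (4654096), genes with reads (15134) and the third principal component (17.8). Cortex control 3 stood apart in genes with reads (19688), the third principal component (-46.9) and ENSRNOG00000053562 (880.9). Hippocampus control 2 stood apart in its position between the tissues (0.427) and in ENSRNOG00000053562 (230.9). The unassigned library, used in no comparison, lay at 0.9 on that scale, far from the cortex end where most cortex libraries lay.

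Hippocampus control 2 and hippocampus 24 h replicate 2 lay between the tissues, and cortex tissue in the dissected piece is a candidate explanation for both. Genes high in hippocampus and genes high in cortex gave positions that differed by 0.05 in the first and 0.06 in the second, as a mixture needs, though single genes of control 2 ranged widely (quartiles -0.01 and 0.85 for hippocampus-high genes). A cortex library under the label of control 2 stays open. Its hippocampus-high genes lay at 0.4, above the highest cortex library at 0.2 but within that spread of genes. Over all genes control 2 correlated more with cortex (mean r 0.9315) than with hippocampus (0.8874). Hippocampus 24 h replicate 2 did so too, by less (0.9312 and 0.9141). Both hippocampus means are lowered by hippocampus control 1, whose own mean r with that tissue was 0.7804. They therefore cannot tell whether the leaning to cortex is particular to control 2. Exposure cannot account for control 2 at 0.43, since that rat was unexposed, and for the 24 h library it cannot be told apart with so few libraries (exact permutation p = 1). Exchanging the labels of control 2 and cortex control 3 raised the genes called between tissues from 436 to 850, but an exchange would need hippocampus-high genes to be raised in cortex control 3, where they lay at 0.04.

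Cortex control 3 lay off its tissue's end in another way. Its cortex-high genes lay at 0.8 and its hippocampus-high genes at 0.04, a difference of 0.76, which argues against hippocampus tissue in that piece.

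Hippocampus control 1 had the fewest genes with reads. Lower depth does not account for it, since the other 9 hippocampus libraries thinned to its depth had 17083 to 17467 genes. A few genes taking most of the reads is argued against by its 10 highest genes, which held 16% of the values, within the 14.7% to 27% of the others. Genes with a mean of 1000 to 2000 spread 2.37 times as much as in the most variable of the other libraries thinned to the same number of genes (1.06 against 0.445 on the log2 scale). This argues against few starting molecules as the whole cause only where each was read evenly. Thinning draws reads independently, so it cannot exclude few molecules that were amplified unevenly. RNA quality, library preparation and a difference of this rat stay open and were not tested.

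The excess of small p-values in cortex between 48 h and 24 h was seen with the spread estimated in cortex (1675 genes) and not with all 20 libraries in the fit (697, against about 751 by chance). The latter fit also takes its spread from the more variable hippocampus controls. In the cortex fit the excess was larger than in any other of the 10 splits of these 6 libraries, where the highest was 694 (1 of 10 gave as many, the real one), but 10 splits are too few for a share under 0.05. Without both doubted cortex libraries 2105 genes had a p under 0.05. Without 24 h replicate 3 alone, the only one in this comparison, the number was 994, against 739 expected. These 2 libraries had low weights (0.169 and 0.187), so leaving them out can raise the number through a smaller spread. It therefore cannot exclude them as a cause. With the position as a covariate the number was 1765, so it did not fall to the 739 expected. In cortex at 24 h against control, mean positions were alike (0.128 and 0.131), yet this covariate raised the number from 1177 to 2014. The number can thus rise through a smaller spread, so it cannot exclude dissection along the cortex to hippocampus scale. The doubted libraries, dissection, the time since exposure, and a handling difference between the days of collection that goes with that time stay open.

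In the counts of splits given here the real split is included. Between control tissues, 2 of 35 splits gave at least 436 called genes, the real one and, at 850, the exchange named above. The splits alone thus do not exclude chance at a share of 0.05, but 430 and 435 of the 436 genes had the same sign in the other rats at 24 h and 48 h, which argues against it, though genes are not independent. Chance could not be excluded for 8 comparisons of exposure. For unadjusted p under 0.05 in cortex, 11 of 35 splits gave as many genes at 24 h (1177, highest other 2207), 10 of 35 at 48 h (515, highest 1612) and 44 of 100 drawn for both times together (578, highest 1890). In hippocampus these were 26 of 35 at 24 h (320, highest 2080), 28 of 35 at 48 h (241, highest 1503) and 35 of 100 drawn for both times (480, highest 2568). For the differences between tissues, splits moved libraries with the same replicate number together, as if from 1 rat, which the labels do not state. There 25 of 35 splits gave as many at 24 h (522, highest 3015) and 33 of 35 at 48 h (198, highest 1466). Hippocampus at 48 h against 24 h has 10 splits, too few for a share under 0.05, and all 10 gave as many (25, highest 1897). That highest split, 24 h replicate 4 with 48 h replicates 1 and 2 against the rest, parts the libraries as the third principal component does (-33.7, -22.7 and -27.1 against 43.8, 43.9 and 49.8). The same values make both, so this describes a structure of these libraries apart from exposure time and does not explain it. For the other comparisons with splits of several times the real number, no such structure was looked for.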

How the results depend on the processing

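Library weights, leaving out doubted libraries and the position covariate were chosen after seeing the data. Over the 8 exposure comparisons within a tissue, 116 of 126 fits other than those leaving out 1 library called 0 genes, and every fit leaving out 1 library called 0 genes, as it did for both differences between tissues. DESeq2 called 41 genes in cortex at 24 h, 2 at 48 h, 145 between the times, 2 in hippocampus at 24 h, 3 at 48 h, 1 between the times and 9 for both times together. Library weights gave 1 in cortex at 48 h and 1335 between the times, and leaving out doubted libraries gave 5 between the times. In the weighted cortex fit, 48 h replicate 2 had the largest weight (5.83). The control tissue comparison moved from 436 to 1515 with DESeq2, 3785 with library weights, 2542 without doubted libraries and 94 with only the compared groups in the fit, and ranged from 76 (without cortex control 2) to 1349 (without hippocampus control 2). DESeq2 made more false calls than limma in simulated data, and the cause of the other differences was not tested. The correlation of the changes at both times moved with the controls split into pairs, to -0.188 in cortex and 0.0627 in hippocampus, where no control library is shared. Whether the replicate numbers pair the libraries stayed unclear. Of the cross-tissue pairs, 3 of 10 with the same number and 5 of 24 with other numbers correlated over 0.1. Within a tissue, pairs came from different exposure groups and so from different rats. There 4 of 8 pairs with the same number passed 0.1 in each tissue, and 7 of 25 with other numbers. With the replicate block, 0 genes were called within each tissue, and 2 between control tissues, where both named IDs lost their call and the block also takes up degrees of freedom. Of 89 fits of the 4 named IDs, 0 changed direction and 19 lay on the other side of the threshold. The set tests of the 37 fixed gene lists were not run, for want of gene names. The settings tested 10645 to 22389 genes in cortex and 10870 to 22050 in hippocampus, so the number expected by chance differs between them. The numbers at an unadjusted p under 0.05 moved more than the calls. Over all settings except those leaving out 1 library they ran in cortex from 425 to 2781 at 24 h, 152 to 1873 at 48 h, 697 to 4115 between the times and 176 to 1798 for both times. In hippocampus they ran from 195 to 1616, 142 to 741, 13 to 1716 and 314 to 1360. All 20 libraries in the fit gave the lowest in cortex, and library weights or DESeq2 the highest in each. With the replicate block they were 784 in cortex at 24 h, and 671 in hippocampus at 48 h and 109 between the times. Precision is limited by the spread between libraries.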

Other observations

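The unassigned library, titled as hippocampus at 24 h and labelled as cortex, had 12787921 reads and reads in 18764 genes. Its position was 1 from hippocampus-high genes and 0.87 from cortex-high genes. Its normalized read count was 38.2 for ENSRNOG00000005670 and 158.1 for ENSRNOG00000053562.

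ENSRNOG00000053562, high in cortex, took separate levels within hippocampus. It was at 95.9 in 24 h replicate 2, 86 in 24 h replicate 3 and 97.3 in 48 h replicate 3, and at 230.9 in control 2. In the other 6 hippocampus libraries with a group it was between 0 and 5.45. The third principal component was 43.8, 43.9 and 49.8 in the first 3 of these libraries, and -12.9 in control 2. These levels did not follow the exposure groups, and were not tested.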
